A study of Mus musculus with 2 samples.

How the data were processed

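Total RNA was prepared from dissected, homogenised dorsal striatum with an Agilent Nanoprep kit, per the labels' protocols, and sequenced as 1 library per group. The mice were of the Drd1-TRAP line CP73, on a mixed FVB/N and Swiss Webster background crossed to C57BL/6 for at least 9 generations, per the labels. The authors aligned reads with STAR 2.0.0e to the mouse genome build mm10 and counted them with HTSeq, per the submitters' processing notes; the HTSeq version, the strand setting and the gene annotation are not given in the sources used here. The deposited values are raw read counts per gene symbol, not normalised. Each group's library was taken from its title, and neither library was left out.

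The deposited counts also list reads given to no gene, which stayed out of library sizes and calls. Of all reads listed, 53.8% in the escalating library (exact 95% binomial interval 53.8 to 53.9) and 55.3% in the nonescalating library (55.3 to 55.3) were assigned to a gene. Reads in no annotated gene made up 28.6% and 18.1%, reads in more than 1 gene 8.06% and 18.9%, and reads aligned to more than 1 place 9.53% and 7.78%. The assigned totals were 9548358 and 9376097 reads. A count of 0 allows up to 3 counts, which is 0.277 CPM in the escalating and 0.363 CPM in the nonescalating library after scaling. These intervals and floors cover counting error only.

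A few symbols took much of the assigned reads. AK140265, known here only by its sequence identifier, held 9.66% of assigned reads in the escalating library (9.64 to 9.68) and 24.1% in the nonescalating library (24.1 to 24.2), and the ribosomal RNA precursor Rn45s held 5.15% (5.13 to 5.16) and 2.97% (2.96 to 2.98); both were picked after their values were seen. The 10 genes with the most reads held 20.2% and 33.0%. Library sizes were therefore scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.13 for the escalating and 0.882 for the nonescalating library. CPM values here are relative to the scaled sizes.

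For each gene with at least 50 counts over both libraries, the log2 ratio of escalating over nonescalating was computed with a pseudocount of 0.5, and folds in the text are ratios of CPM without a pseudocount. The 95% interval of each ratio is the exact Clopper-Pearson interval for the split of the gene's counts between the libraries. Folds against a count of 0 use the floor of 3 counts. No test between groups can be made with 1 library per group, so edgeR's and DESeq2's tests were not run. A gene was called at 1.5-fold with an interval that excluded 1.

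A list's median was placed among 10000 random lists of the same size, in which each member was replaced by 1 of the 200 genes nearest in mean expression, and it stood apart below percentile 2.5 or above 97.5. This describes these libraries and is not a test of the conditions. There were 34 lists fixed before the data were examined, which took in markers of other cell types and regions; 6 had fewer than 5 measured members and were given no percentile. The mitochondrial genome list matched no symbol in the deposited counts. The text names, by a rule also fixed beforehand, the 12 genes in each direction with the largest interval bound nearest to 1 among genes with at least 100 counts, the 4 members of each list with the largest ratio in size (a selection of these is printed), and 12 genes always reported. The always reported genes are Drd1, Drd2, Tac1, Pdyn, Penk, Fos, Fosb, Arc, Egr1, Npas4, Xist and Ddx3y. Genes named outside the rule are said to be so, and the values of a few genes that the rule names are not reported here.

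Coordinates, transcript length, GC content and overlaps between genes came from GENCODE M21, which is on the same build as mm10. It matched 73.5% of the symbols and gave length and GC content for 95.7% of measured genes. A predicted hydrophobic segment was a window of 19 residues with a mean Kyte-Doolittle value of at least 1.6 in the longest open reading frame of a coding transcript. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

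The calls were tested on simulated data with the real means and library sizes of the 12213 genes in this comparison and counting noise only. Of genes set to differ, 96.0% were recovered at 2-fold and 100% at 4-fold, 0.874% of unchanged genes were called, and 95.5% of intervals held the true ratio. Of unchanged lists 4.0% stood apart, and of lists raised by 0.5 log2 100% did. The simulation holds no variation between animals, so these rates do not apply to the difference between the conditions. Alternatives were other scalings (DESeq2 1.42.0 size factors, total reads, TMM without haemoglobin and ribosomal protein genes), filters, pseudocount, thresholds and ways of drawing random lists.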

Results

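Dorsal striatum RNA was profiled in mice that had taken cocaine by intravenous self-administration in long daily sessions. The animals carried the Drd1-TRAP transgene (line CP73), which puts an EGFP-tagged copy of the ribosomal protein Rpl10a into cells that express the dopamine receptor Drd1, so that their ribosomes can be purified. Both libraries came from the input, that is, the total RNA of the dissected tissue and not the purified ribosome fraction. There was 1 library from the group whose intake escalated and 1 from the group whose intake did not, and the number of animals behind each library was not given in the sources used here. The escalating library held 9548358 reads assigned to genes and the nonescalating library 9376097. A read was present for 18630 genes in the former and 18638 in the latter.

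The comparison asked which transcripts differ in dorsal striatum between mice that escalate their cocaine intake and mice that do not. Microglial genes showed the widest gap: all 18 measured members of the microglia list were lower in the escalating library, with a median log2 ratio of -5.63. Astrocyte genes followed, with all 17 lower and a median of -1.47, and 11 of 18 mature oligodendrocyte genes and 12 of 15 endothelial genes were lower as well. In the other direction, 7 of 13 glucocorticoid-responsive genes and 6 of 16 circadian clock genes were higher in the escalating library, with medians of 0.83 and 0.43. Markers of the projection neurons that express Drd1 and of those that express Drd2 had medians of -0.06 and -0.30 (0.30 and 0.06 when scaled to total reads) and did not stand apart from genes of like expression.

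With 1 library per group, no difference reported here has a replicate check, and no p-value is given. The interval of each gene's ratio is a 95% counting interval (exact, Clopper-Pearson). It covers counting error only and may be too narrow, since reads are not independent molecules. Each value compares these libraries and not the conditions. A gene was called higher or lower when its ratio was at least 1.5-fold and its interval excluded 1. Among 12213 genes with at least 50 counts over both libraries, 1143 were higher and 2085 lower in the escalating library. The share of calls that were higher was 35.4% with TMM scaling and 77% when counts were scaled to total assigned reads alone, where 3853 genes were higher and 1148 lower. The scalings differ in their centre: the median log2 ratio over all measured genes was 0.02 with TMM and 0.38 with total reads, so ratios below are relative to the TMM centre. Differences of at least 4-fold were found for 312 of the genes called lower and 18 of those called higher. Across genes, which are not independent replicates, log2 expression in the libraries correlated with Pearson's r = 0.928.

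**Figure D1:**
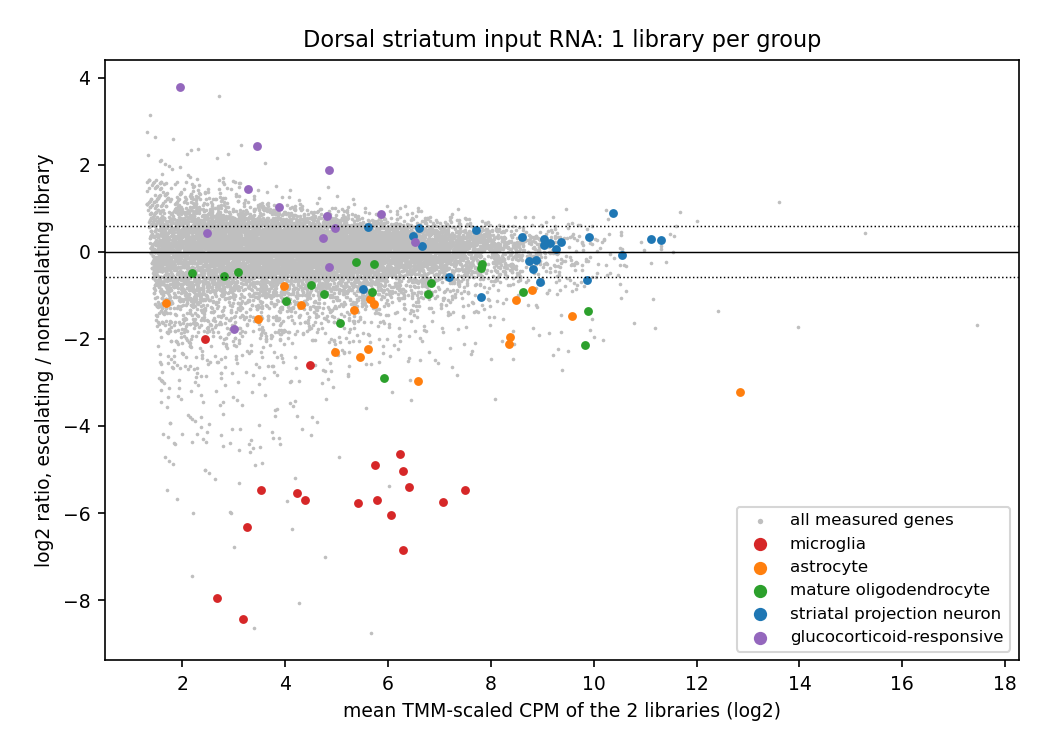
Each point is 1 of the 12213 measured genes, with the mean TMM-scaled CPM of the libraries on the horizontal axis (log2) and the log2 ratio of the escalating over the nonescalating library on the vertical axis; dotted lines mark 1.5-fold and colours mark members of 5 gene lists. Microglial genes lie around a median of -5.63 and astrocyte genes around -1.47, while striatal projection neuron genes lie around 0.18.

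The genes with the largest differences in the lower direction were named by the interval bound nearest to 1, and 7 of these 12 belonged to the microglia list. Itgam, an integrin subunit of myeloid cells (chromosome 7, 128062640 to 128118491), had 14 counts in the escalating and 1276 in the nonescalating library, which was 119-fold lower (interval 70.8 to 219). Csf1r, the receptor for the growth factor on which microglia depend (chromosome 18, 61100598 to 61132149), had 86 and 2933 counts and was 44.6-fold lower (36.0 to 55.9). The lysosomal protease gene Ctss was 54.1-fold lower (41.2 to 72.4), with 53 and 2192 counts, and the complement gene C1qc was 53.6-fold lower (35.2 to 85.9). P2ry12, a purinergic receptor of resting microglia, was 67.8-fold lower (44.1 to 110.0), with 21 and 1089 counts. P2ry13 had 2 and 844 counts and was 552-fold lower (152 to 4565), and Ly86 had 1 and 320 counts and was 419-fold lower (74.6 to 16581). Olfml3 and Cd180 were 147-fold (57.2 to 544) and 93.8-fold lower (36.3 to 347). Trem2, C3ar1 and Gpr34 had no count in the escalating library and 106, 173 and 149 in the nonescalating library. Set against a floor of 3 counts, they were at least 46.2-fold, 75.4-fold and 65.0-fold lower, while the wider interval used for ranking has bounds of 36.9-fold, 60.7-fold and 52.2-fold. P2ry12 and P2ry13 lie within Med12l, Gpr34 within Cask, and Cd180 and Csf1r overlap Mast4 and Hmgxb3, each on the opposite strand; the strand setting of the counting was not given in the sources used here.

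The 12 genes named by the same rule in the higher direction differed by less. Gbp4, an interferon-inducible GTPase (chromosome 5, 105115767 to 105139586), had 131 and 8 counts and was 12.5-fold higher in the escalating library (6.17 to 29.6), but it overlaps its relatives Gbp8 and Gbp9 on the same strand, so its count is uncertain. Zbtb16, a transcription factor induced by glucocorticoids (chromosome 9, 48654297 to 48836222), was 5.43-fold higher (3.65 to 8.39), with 199 and 28 counts. The purine-degrading enzyme gene Xdh was 5.60-fold higher (3.57 to 9.18), and the collagen gene Col6a4 was 4.81-fold higher (3.02 to 8.02). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), was 3.70-fold higher (2.99 to 4.63), with 494 and 102 counts. Hif3a, a hypoxia-inducible factor subunit, was 4.14-fold higher (2.93 to 5.98), and the carbonic anhydrase gene Car7 was 4.55-fold higher (2.78 to 7.83). Sncb, which encodes beta-synuclein, was 2.81-fold higher (2.30 to 3.46). The nuclear noncoding RNA Malat1 was 2.20-fold higher (2.18 to 2.22), with 184353 and 63970 counts. Npas4, an activity-induced transcription factor (chromosome 19, 4984355 to 4990316), was 2.85-fold higher (2.14 to 3.84). Trmt10a, a tRNA methyltransferase gene that overlaps Mttp on the opposite strand, was 3.26-fold higher (2.13 to 5.15). The remaining gene, 3000002C10Rik, was 5.29-fold higher (2.94 to 10.3) and is annotated as a processed pseudogene, so its reads may be shared with a parent gene.

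**Figure D2:**
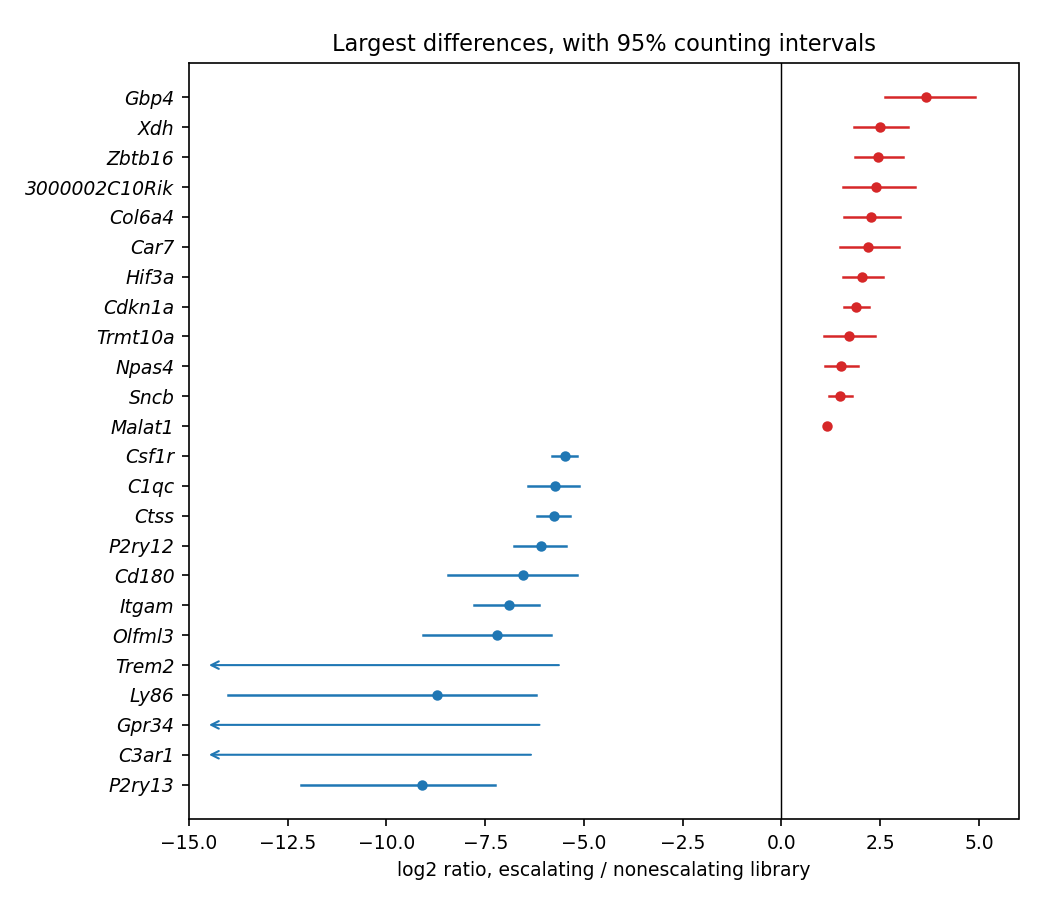
Log2 ratio of the escalating over the nonescalating library for the 12 genes with the largest difference in each direction (points), with 95% counting intervals (lines); arrows start at the ratio that a floor of 3 counts gives for genes with no count in the escalating library. These genes have at least 100 counts and were ranked by the interval bound nearest to 1; in the lower direction they differ by 44.6-fold or more, and in the higher direction by 12.5-fold (Gbp4) or less.

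Of 34 gene lists fixed before the data were examined, 28 had at least 5 measured members and were compared with 10000 random lists of genes of like expression. The median stood apart in the lower direction for 11 lists and in the higher direction for 4, and did not stand apart for 13. Standing apart was common between these libraries. Of 131 families of genes with a shared symbol stem, scanned after the data were seen, 23 lay below and 18 above the same bounds.

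Most glial and vascular lists were lower. The medians of the microglia, astrocyte and endothelial lists lay below every one of the 10000 random lists (percentile 0), and that of the mature oligodendrocyte list lay at percentile 0.01. With the 2 microglial genes that had no count placed at the floor, the microglia median was -5.54. Among astrocyte genes, the glutamate transporter Slc1a2 was 9.33-fold lower (9.18 to 9.49), with 15371 and 109677 counts, the water channel Aqp4 7.89-fold (6.87 to 9.10), the gap junction gene Gja1 5.37-fold (4.48 to 6.47) and Fgfr3 4.94-fold (4.01 to 6.13). Among myelin genes, Bcas1 was 7.5-fold lower (6.31 to 8.96), Mbp 4.42-fold (4.26 to 4.59) and Ugt8a 3.13-fold (2.62 to 3.76). The endothelial genes Itm2a and Pltp were 4.45-fold (3.25 to 6.19) and 3.86-fold lower (2.86 to 5.26). In the oligodendrocyte precursor list, 4 of 10 genes were lower and 1 higher (median -0.45, percentile 1.77); Pdgfra was 2.11-fold lower (1.82 to 2.45) and Neu4 1.75-fold higher (1.2 to 2.58). This list no longer stood apart under 4 alternative settings, such as a filter of 10 counts (percentile 6.06) or the mean of members (9.5). In the mural and meningeal list, 3 of 7 genes were lower (median -0.73, percentile 1.27), among them Vtn at 3.60-fold (2.77 to 4.73); it did not stand apart by the mean (4.24). With total-read scaling the medians of these lists kept their sign, and the members called lower were 15 of 17 for astrocytes, 7 of 18 for mature oligodendrocytes, 8 of 15 for endothelium, 2 of 10 for oligodendrocyte precursors and 18 of 18 for microglia.

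The integrin, axon guidance, interferon and MHC, GABA receptor and ribosomal protein lists also stood apart in the lower direction. In the integrin list 11 of 14 genes were lower (median -1.23, percentile 0), including the leukocyte subunit Itgb2 at 26.0-fold (12.9 to 61.3), Itgb5 at 10.9-fold (7.58 to 16.2) and Itga6 at 5.21-fold (3.84 to 7.18); Itgam belongs to this list and to the microglia list. In the axon guidance list 20 of 59 genes were lower and 3 higher (median -0.44, percentile 0), with Plxnb1 5.40-fold (4.74 to 6.16), Sema4a 4.05-fold (3.04 to 5.45) and Plxnb2 3.57-fold lower (3.0 to 4.26). The interferon and MHC list had 6 of 10 genes lower and 1 higher (median -0.88, percentile 0.22, or 7.77 by the mean). Its class I members B2m and H2-D1 were 7.72-fold (6.68 to 8.97) and 3.24-fold lower (2.47 to 4.28), and Oasl2 was 4.03-fold higher (2.10 to 8.52). Of GABA receptor genes 5 of 15 were lower (median -0.54, percentile 0.16, or 5.12 against genes matched on a predicted hydrophobic segment, a setting added after the data were seen), with Gabrg1 at 2.54-fold (2.0 to 3.25). Of ribosomal protein genes 19 of 78 were lower (median -0.42, percentile 0), with Rpl23a at 2.13-fold (1.76 to 2.59). With total-read scaling the GABA receptor and ribosomal protein medians were -0.18 and -0.05. In each list 1 gene was still called lower, and 1 ribosomal protein gene was called higher. Under the same scaling 7 integrin genes were lower (median -0.88), 11 axon guidance genes were lower and 4 higher (median -0.09), and 5 interferon and MHC genes were lower and 3 higher (median -0.53). Beside these groups, the microglia and astrocyte lists had medians of -5.63 and -1.47.

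Genes that respond to glucocorticoid hormone were higher as a group, with 7 of 13 higher, 1 lower and a median above every random list (percentile 100). The lipid droplet gene Plin4 had 79 and 4 counts and was 15.1-fold higher (5.67 to 56.8), and Zbtb16 and Cdkn1a belong to this list too. Pdk4, a mitochondrial kinase gene of the same list, was 3.45-fold lower (2.37 to 5.13). Of circadian genes 6 of 16 were higher and 0 lower (percentile 100), with Ciart 2.70-fold (2.08 to 3.53), Dbp 2.51-fold (1.74 to 3.69), Per3 2.08-fold (1.84 to 2.37) and Cry2 1.82-fold higher (1.68 to 1.97). The time of day of collection was not given in the sources used here. Of oxidative phosphorylation genes 9 of 76 were higher (median 0.17, percentile 99.5, or 96.6 against genes matched on length and GC content), with Ndufa11 at 1.65-fold (1.23 to 2.24). Over all measured genes 1143 of 12213 were higher. Of small nucleolar RNA host genes and nuclear noncoding RNAs 4 of 14 were higher (median 0.33, percentile 98.6, or 96.96 with a filter of 10 counts), with Meg3 at 1.89-fold (1.86 to 1.92). With total-read scaling more members of these lists were higher: 11 glucocorticoid-responsive, 11 circadian, 34 oxidative phosphorylation and 9 small nucleolar host and nuclear noncoding genes. With a pseudocount of 5, 5 oxidative phosphorylation genes were higher, beside 1075 of all measured genes. The microglia list lay at -5.63 and the astrocyte list at -1.47 beside them.

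**Figure D3:**
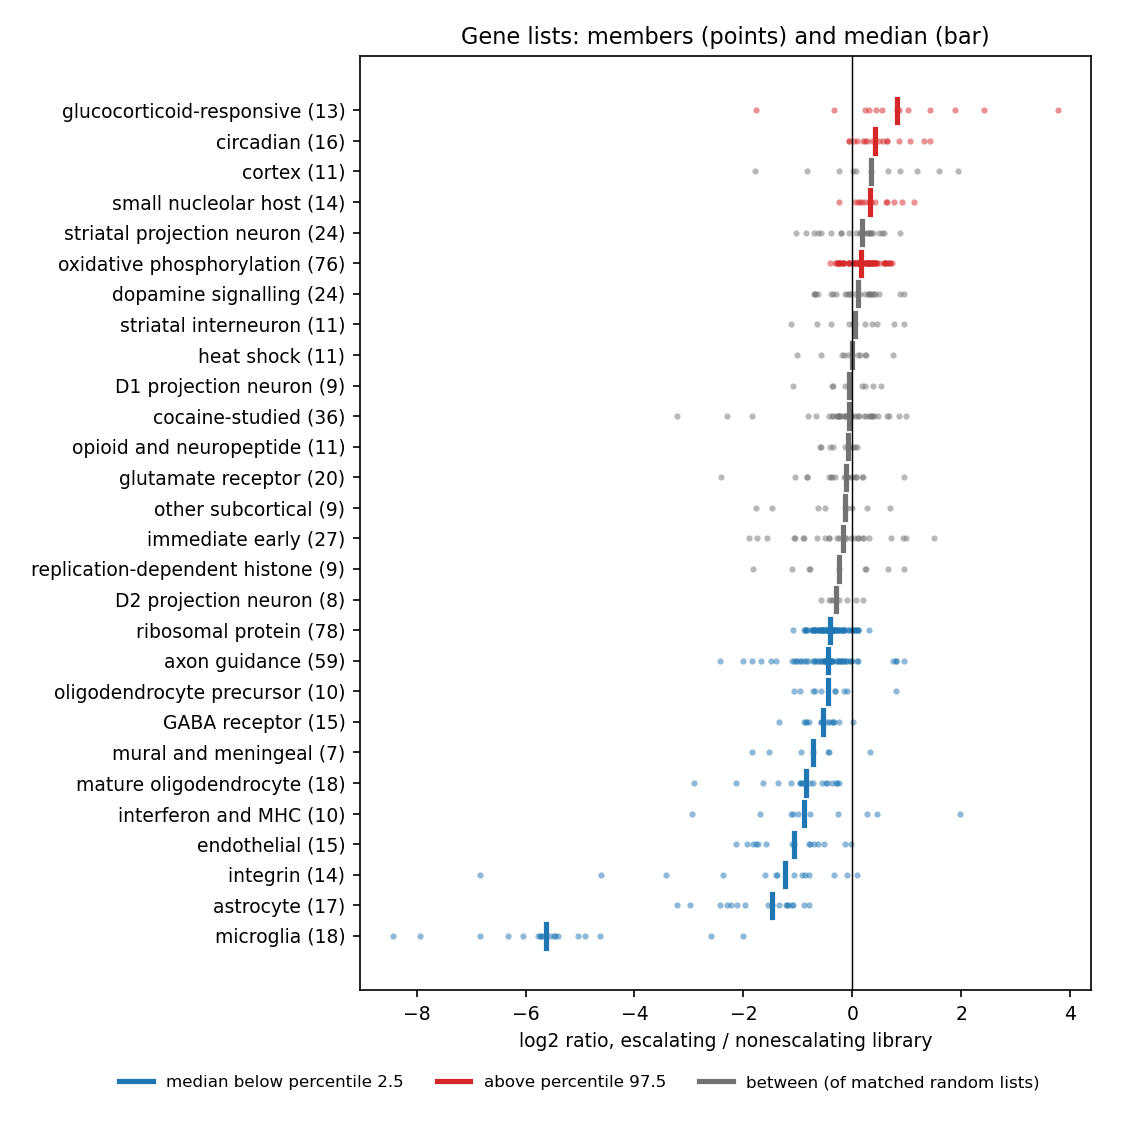
Members (points) and median (bar) of the 28 fixed gene lists with at least 5 measured members, on the log2 ratio of the escalating over the nonescalating library, with the number of measured members in parentheses; colour marks lists whose median lay among the lowest or the highest 2.5% of random lists matched on expression. The medians run from -5.63 for microglia to 0.83 for glucocorticoid-responsive genes.

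Striatal neuron lists did not stand apart in the main setting. Drd1 (chromosome 13, 54051183 to 54055705) had 3010 and 2959 counts and a log2 ratio of -0.36 (-0.44 to -0.29). Drd2 (chromosome 9, 49340627 to 49408177) had 1628 counts in each library and a log2 ratio of -0.39. Both ratios are about the size of the shift from total-read to TMM scaling (-0.36 log2), so they depend on the scaling. The neuropeptide genes Tac1, Pdyn and Penk had log2 ratios of -0.06, -0.14 and -0.57, of which those of Tac1 and Pdyn became positive with total-read scaling. None of the 5 genes reached 1.5-fold. In the D1 list 1 of 9 genes was lower and 0 higher (1 and 3 with total-read scaling; percentile 31.1), and in the D2 list 0 of 8 (percentile 8.37). The list shared by both kinds of projection neuron had 1 gene higher and 4 lower of 24 (median 0.18, percentile 95.7). It stood apart, at percentile 97.7, against genes matched on a predicted hydrophobic segment, a setting added after the data were seen. Its member Ppp1r1b, which encodes DARPP-32, was 1.84-fold higher (1.79 to 1.89), while the adenylyl cyclase Adcy5 was 1.63-fold lower (1.56 to 1.69). With total-read scaling Adcy5 was not called, and 11 genes of this list were higher and 1 lower. Of interneuron genes 2 of 11 were higher and 2 lower (5 and 1 with total-read scaling; median 0.06, percentile 53.6), with Th 1.95-fold higher (1.34 to 2.89) and the glutamate transporter Slc17a8 2.19-fold lower (1.74 to 2.76).

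Activity-induced genes went both ways. In the immediate early list 4 of 27 genes were higher and 8 lower (5 and 5 with total-read scaling; median -0.18, or 0.18 with that scaling; percentile 8.63). Npas4 was higher, as above, while Arc (chromosome 15, 74669083 to 74672570), with 224 and 637 counts, was 3.72-fold lower (3.19 to 4.35), Nptx2 3.41-fold lower (2.38 to 4.96) and Egr2 3.0-fold lower (2.06 to 4.44). Egr1 and Fosb had log2 ratios of -0.18 and 0.31, under the 1.5-fold threshold; with total-read scaling the ratio of Egr1 became positive and Fosb was called higher. Fos had 15 and 18 counts, too few for a difference of this size to be detectable at this depth.

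The dopamine signalling, neuropeptide and glutamate receptor lists did not stand apart. Of dopamine signalling genes 2 of 24 were higher and 4 lower (10 and 0 with total-read scaling; median 0.10, percentile 83.1), and of opioid and neuropeptide genes 1 of 11 was lower (0 with total-read scaling; median -0.09, percentile 28.5). Of glutamate receptor genes 1 of 20 was higher and 4 lower (1 and 2 with total-read scaling; median -0.12, percentile 19), with Grin2c 5.36-fold lower (3.91 to 7.49). Among 36 measured genes picked beforehand because cocaine research has studied them, 4 were higher and 5 lower (11 and 3 with total-read scaling; median -0.07, percentile 20.7). The BDNF receptor gene Ntrk2 was 3.57-fold lower (3.43 to 3.72) and the cystine transporter gene Slc7a11 4.96-fold lower (4.08 to 6.07). Slc1a2, given above, is in this list and in the astrocyte list, whose median was -1.47. Whether Grin2c, Ntrk2 and Slc7a11 were lower along with the astrocyte genes was not tested. Heat shock genes had 1 higher and 1 lower of 11 (3 and 1 with total-read scaling; median -0.01, percentile 50.8), the lower one being Hspa5 at 2.02-fold (1.87 to 2.19). Replication-dependent histone genes had 1 higher and 4 lower of 9 (4 and 2 with total-read scaling; median -0.24, percentile 22.4). The negative medians of the immediate early, D1, D2, opioid, glutamate receptor, cocaine-studied, heat shock and histone lists all became positive with total-read scaling.

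Markers of neighbouring regions were mixed. Whether the lower ones, such as Rorb, Prkcd and Lhx2, fell along with the glial genes was not tested. In the cortex list 5 of 11 genes were higher and 2 lower (median 0.35, percentile 96.7). Neurod6 was 3.94-fold higher (2.16 to 7.78), Tbr1 3.04-fold (2.08 to 4.53) and the vesicular glutamate transporter Slc17a7 2.29-fold (1.82 to 2.92), but Rorb was 3.47-fold lower (3.13 to 3.85). Under 7 of the alternative settings this median lay among the highest 2.5% of random lists, and so stood apart, while with a filter of 200 counts the median was 0.04, at percentile 54.3. In the list for other subcortical regions 0 of 9 genes were higher and 3 lower (2 and 2 with total-read scaling; median -0.13, positive with total-read scaling; percentile 22.1), with Prkcd 3.42-fold lower (2.49 to 4.76) and Lhx2 2.79-fold lower (2.38 to 3.27).

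Lists with fewer than 5 measured genes are given by their members. Of choroid plexus genes Clic6 was 2.01-fold higher (1.58 to 2.58) and Enpp2 2.45-fold lower (2.23 to 2.68), and the ependymal gene Foxj1 was 1.73-fold higher (1.11 to 2.76). Whether Enpp2 was lower along with the glial genes was not tested. The haemoglobin gene Hbb-bs was 3.62-fold lower (2.76 to 4.80), with 73 and 202 counts. Xist had 7 and 3 counts, and the Y-linked Ddx3y had 444 and 311 counts with a log2 ratio of 0.13, so both libraries carried Y-linked transcripts at a similar level. None of the 4 measured sex-linked genes was called, although Eif2s3y was called higher with total-read scaling. Of 4 measured genes that vary between mouse strains, Gabra2 was called, at 1.74-fold lower (1.47 to 2.07), and this call was lost with total-read scaling.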

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

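Of the tests in this part, those of a single lower share of glia, of both forms of a pull-down fraction, of glucocorticoid-responsive against neuronal genes and of channel and receptor lists without glial members were chosen only after the result was seen. The correlations of the ratio with GC content and length over all genes (Spearman 0.07 and -0.12) had been seen before the tests of length and GC bias were set, but not the matched values.

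Reads that the counting gave to no gene lie outside every comparison above and differ between the libraries. Reads in no annotated gene were 28.564% of the escalating and 18.066% of the nonescalating library. Reads in more than 1 gene were 8.064% and 18.858%. Reads aligned to more than 1 place were 9.53% and 7.781%. They are listed because they were not analysed further, and no explanation for the differences was tested.

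Glial and above all microglial transcripts were lower in the escalating library. Length or GC bias is argued against: the microglia list still lay at -5.71 log2 from lists matched on expression, length and GC content. Microglial and astrocyte genes did not fall by a common amount: even the 90th percentile of microglial genes lay at -2.56 relative to the astrocyte median. The difference of medians was -4.16 (bootstrap interval -4.56 to -3.31). This comparison was chosen with both medians known. It restates that gap and does not test a single lower share of all glia. For a Drd1 pull-down fraction in place of the input, D1 against D2 markers left it open, at 0.235 (-0.26 to 0.63). A second comparison was chosen because the first was undecided and with both medians already known. Its outcome was thus fixed, and it cannot decide the question: markers of the untagged D2 neurons lay 5.33 log2 above microglial genes (4.96 to 5.77). A Drd1 pull-down fraction, in whole or in part, stays open. So do a real difference between the groups, a separate loss in each cell type and a difference in handling. Group and library are the same here, so none of these can be told apart.

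Glucocorticoid-responsive genes were higher in the escalating library. Length or GC bias is argued against, as the list stayed 0.76 log2 above matched lists. Fewer glial cells leaving a higher share of neuronal transcripts stay open. The list lay 0.65 log2 above the striatal projection neuron list (0.08 to 1.33), an interval that comes close to 0. Both medians were known when this comparison was chosen, so it does not test that explanation. Without the clock gene in the list, 12 members had a median of 0.85, and 15 circadian genes without it had a median of 0.48, both at percentile 100. A hormonal difference between the groups, the time of collection and stress at collection may each contribute and were not tested.

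Transcripts of membrane and secreted proteins were lower in the escalating library relative to other coding genes, a pattern noticed while scanning 131 families of gene symbols in the same data; with total-read scaling the median of genes with a predicted hydrophobic segment was 0.10, against 0.47 without one. Length or GC bias is argued against, since genes with a predicted hydrophobic segment lay -0.35 log2 from those without one (-0.37 to -0.32) after matching. Fewer glial cells remain open: the bound set beforehand was met by the whole potassium channel list (percentile 1.01), but that list proved to hold the glial genes Kcnj10, Kcnj16, Kcnk13 and Kcnk6, which a loss of glia lowers too, and without these 4, left out after their values were seen, it lay at 5.66, while GABA receptor genes without 5 also found in glia lay at 2.26. Less RNA from ribosomes bound to the endoplasmic reticulum is a candidate explanation whose lists were chosen after the scan had shown solute carriers as a whole to be low (median -0.33), but before they were split: mitochondrial carriers, made in the cytosol, lay 0.43 log2 above the others (0.32 to 0.64), and endoplasmic reticulum proteins lay at percentile 0. Some of the other solute carriers are glial, so this remains a hypothesis found and tested on the same data, and a biological difference between the groups stays open.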

How the results depend on the processing

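The alternative that matches random lists on a predicted hydrophobic segment was chosen after seeing the data; the others were planned. No named gene call and no fixed list's call turned to the opposite direction, although some calls were lost or gained. The balance of called genes turned with total reads, from 35.4% to 77% higher. Genes higher in the escalating library numbered 3853 with total-read scaling, 578 with at least 200 counts, 249 at 2-fold and 230 with the 1.5-fold threshold on the interval bound, against 1143; genes lower numbered 1148, 1253, 1085 and 1212 under the same settings, against 2085. The last 3 settings are stricter or hold fewer genes by construction, and total-read scaling shifts the centre of the ratios by 0.36 log2. Lists standing apart numbered 13 to 16 across alternatives, against 15. With at least 200 counts the mural and histone lists had too few members for a percentile. The cortex list came to stand apart under 7 alternatives, for example at percentile 97.53 with total reads, 98.01 with length and GC matching and 98.48 with the mean. Calls were lost for oligodendrocyte precursors (6.06 at 10 counts or no filter, 9.50 with the mean), small nucleolar hosts (96.96 at 10 counts), oxidative phosphorylation (96.55 with length and GC matching), and mural and interferon lists (4.24 and 7.77 with the mean); with hydrophobic matching, precursors lay at 15.83, mural genes at 4.60, GABA receptors at 5.12 and small nucleolar hosts at 87.70, and striatal projection neurons came to stand apart at 97.70; the cause was not tested. The microglia, astrocyte, circadian and glucocorticoid lists kept their call under every alternative. Over 4 alternatives, a named gene kept its status, called or not called, in 689 cases. A call was lost in 18 cases and gained in 13, of which 17 and 11 came with total-read scaling. The planned TMM scaling without mitochondrial genes removed haemoglobin and ribosomal protein genes alone, as no mitochondrial symbol matched. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Depth limits genes under 50 counts, while counting error is small for the most abundant genes.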

Other observations

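All gene groups in this part were chosen after the data were seen. Endoplasmic reticulum genes, which encode the translocon, glycosylation and folding machinery, were lower in the escalating library in 20 of 31 cases (median -0.78, percentile 0), with Stt3b 2.37-fold (2.09 to 2.69), Canx 2.25-fold (2.10 to 2.41) and Hsp90b1 2.19-fold lower (2.07 to 2.32). Protocadherins, which are adhesion proteins, were lower in 26 of 54 cases (median -0.58, percentile 0), with Pcdhgc3 at 5.62-fold (4.98 to 6.37). Clustered protocadherins share exons, so single members are uncertain. Whether Pcdhgc3 was lower along with the astrocyte genes was not tested. Solute carriers outside the mitochondrial family were lower in 54 and higher in 5 of 173 cases (median -0.40, percentile 0), while 3 of 35 mitochondrial carriers were lower and 4 higher (median 0.03, percentile 53.8). Potassium channel genes were lower in 11 and higher in 3 of 60 cases (median -0.17, percentile 1.01), with the astrocytic channel Kcnj10 at 7.09-fold (6.40 to 7.88). Over all measured genes 2085 of 12213 were lower. Of 4024 coding genes with a predicted hydrophobic segment 29.3% were lower and 5.22% higher, against 11% and 10.3% of 7370 without one; with total-read scaling the shares were 16.5% and 18.3% against 5.9% and 37.4%. With total-read scaling 7 endoplasmic reticulum genes were lower and 0 higher (median -0.42), 7 protocadherins were lower and 1 higher (median -0.22), and 26 solute carriers outside the mitochondrial family were lower and 16 higher (median -0.05). Potassium channel genes then had 12 higher and 5 lower with a median of 0.19, and mitochondrial carriers 12 higher and 2 lower.

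Proteasome and aminoacyl-tRNA synthetase genes were higher as lists, unlike the ribosomal protein genes described above, which had a median of -0.42. Proteasome genes were higher in 5 of 35 cases and lower in 0 (median 0.26, percentile 99.9), with Psmd9 at 1.93-fold (1.46 to 2.57) and Psmd13 at 1.84-fold (1.44 to 2.38). Cytosolic aminoacyl-tRNA synthetases were higher in 4 and lower in 1 of 20 cases (median 0.32, percentile 99.8), with Yars 1.65-fold (1.44 to 1.89) and Sars 1.62-fold higher (1.43 to 1.86), but Vars 1.76-fold lower (1.22 to 2.54). With total-read scaling 22 proteasome and 12 synthetase genes were higher, and Vars was not called. Single abundant neuronal genes picked after their values were seen also differed: Kif5a, a kinesin heavy chain, was 4.08-fold lower (3.95 to 4.21) and the kinase gene Camk2a 2.14-fold lower (2.10 to 2.18). The symbol DQ539915, known here only by its sequence identifier, was 3.33-fold lower (3.30 to 3.35), with 80626 and 205129 counts.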
